A study of Mus musculus with 10 samples.

How the data were processed

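Gene expression was measured by bulk RNA sequencing of macrophages sorted from aortic plaques of Ldlr-/- mice, which lack the low-density lipoprotein receptor and develop atherosclerosis on a rich diet. The groups were taken from the treatment label: 5 libraries carried the NS (non-specific) control mimic and 5 carried the miR-369-3p mimic, a synthetic copy of a microRNA. Per the submitters' processing notes, the reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b and counted with Subread 1.5.2, with the builds GRCm38 and mm10 named. The strand setting, the annotation release and any removal of duplicates or low counts were not given in the sources used here. The deposited values were raw counts per Ensembl gene, whole numbers with no normalization by the authors, in 10 columns, all of which were used. Counts per library ran from 4001185 to 26011885.

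Ensembl identifiers were matched to GENCODE mouse release M21. Of 49315 identifiers, 49056 matched and 259 did not, and the latter were kept without a name. Genes were filtered with filterByExpr by group, which left 19649 genes for testing, and the libraries were scaled with TMM factors. The main test was the edgeR 4.0.16 quasi-likelihood F test of the miR-369-3p mimic over the NS control mimic, two-sided and without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic, and 95% intervals from the quantile of the t distribution at the fitted degrees of freedom. Levels are given in counts-per-million (CPM) values on TMM-scaled totals unless the total counts are named, as mean ± SD over the 5 libraries of a group. CPM of olfactory receptor genes, of all immunoglobulin genes together and of Sucnr1 were taken on the total counts throughout.

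The comparison, the tests, 37 gene lists and the rule for named genes were fixed before the data were examined. The lists held 21 of macrophage biology, 12 of cell type markers and 4 of library quality, and all 37 had 3 or more tested members. Each list was tested with camera in limma 3.58.1 on voom log2 CPM at a preset correlation between genes of 0.01, adjusted over the 37 lists, and beside it with a correlation estimated per list and with fry, which tests whether the members moved one way on balance. A list score was the mean log2(CPM + 1) of its members. It was compared between groups with a two-sided exact permutation test over 252 labelings, which gives p = 0.00794 at the smallest. Adjusted over 37 lists, a list score could thus pass only if several lists came near that smallest p together. A named set of 13 genes of succinate sensing, succinate dehydrogenase and inflammasome signalling was also adjusted over the list alone. Genes with a match to the miR-369-3p seed in the annotated 3′ UTR were compared with searched genes without one, and the difference was ranked among those of all words of the same base composition.

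The named genes were the 13 of that set, any of up to 12 genes per direction past the threshold, and, where fewer than 5 passed, the 8 genes per direction with the smallest unadjusted p. For the last 2 parts a mean of at least 5 CPM in the higher group was required, and immunoglobulin or T cell receptor segments and names starting with Gm or ending in Rik were left out. Added to these were up to 4 members with the smallest p from each list described, Xist, the Y-linked genes, haemoglobin, a mitochondrially encoded gene and Ldlr. Which lists to describe was settled after their results were seen. The immunoglobulin variable segments, Ighg3, Lyz2, Cd68, Acta2 and Gm10800 fall outside the rule and were picked after their values were seen.

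The alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a filter of 1 CPM in 5 libraries, voom with sample quality weights, the replicate number as a block, each library left out in turn, and other pseudocounts for the list scores. Fits leaving out 2 libraries with many reads on silent genes, or 4 libraries sharing immunoglobulin segments, were added after the data were seen. The 4 were NS control 4 and 5 and miR-369-3p mimic 3 and 4. NS control 2 and miR-369-3p mimic 2, which share the same segments with them, were kept in that fit. Where more than 100 splits of the libraries into 5 and 5 exist (126), 100 were drawn with a fixed seed. The pipeline was tested on simulated data of the same design: it recovered 10% of 50 genes changed 2-fold, 68% at 4-fold, 90% at 8-fold and 98% at 16-fold, with 5 unchanged genes among 138 called. The changed genes were drawn from those with an average level above 5 CPM, and all genes were simulated as independent. The rates therefore do not cover genes at lower levels or genes that vary together. With 138 genes called, the adjustment was also milder than in data with 0 called. The common biological coefficient of variation of the real libraries was 75.8%, and the median SE of a log2 fold change was 0.50. The labels give no batch, date, litter or sex, and nothing in them says that the libraries came from separate mice. Every p of a gene or list score test therefore measures the spread between these samples. Camera at the preset correlation rests mainly on the spread between genes, and the rank p of the seed word on that between words. Intervals on shares and pooled counts cover counting error alone.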

Results

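The libraries were made with an ultra-low-input kit from macrophages sorted from aortic plaque. The mice had received a diet high in fat and sucrose for 8 weeks and then mimic injections for 4 weeks on the same diet, with 2 injections of 2 nmol a week. The 5 NS control mimic libraries held 25883059, 25522110, 24688527, 10221473 and 24221980 counts in the order of their replicate numbers. The 5 miR-369-3p mimic libraries held 19695215, 26011885, 24194084, 22567509 and 4001185. Macrophage transcripts were abundant in both groups. Lyz2, which encodes lysozyme, stood at 16261 ± 4378 CPM of the total counts in NS control libraries and 18387 ± 1679 in mimic libraries (SD, n = 5 each). The macrophage gene Cd68 stood at 746 ± 203 and 773 ± 93.5. NS control 4 and miR-369-3p mimic 5 were the libraries with the lowest totals. They also carried 2998 and 8848 CPM of the total counts on olfactory receptor genes, which macrophages are not known to use. The other 8 libraries carried 97.4 to 728 CPM on them. Reads on Ldlr were present in all libraries, with 137 ± 29.5 CPM in the NS control group and a log2 fold change of −0.39 in the mimic group. Counts over the whole gene do not show whether the deleted part was read, so they do not check the knockout.

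**Figure D1:**
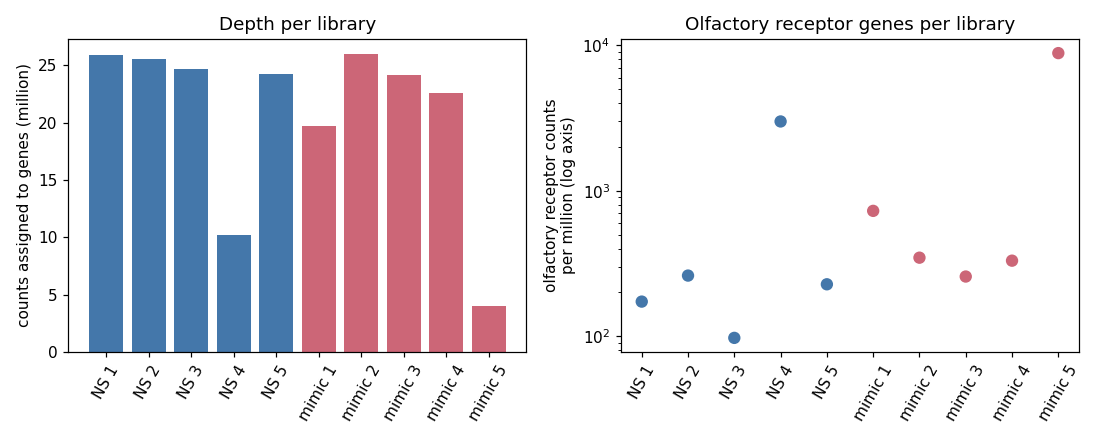
Counts assigned to genes per library (left, bars) and CPM on olfactory receptor genes on a log axis (right, points), with NS control mimic libraries in blue and miR-369-3p mimic libraries in red. NS control 4 and miR-369-3p mimic 5 had the lowest totals, 10221473 and 4001185. They also had the most olfactory receptor reads, 2998 and 8848 CPM of the total counts.

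The comparison of mimic with control asked how miR-369-3p changes gene expression in plaque macrophages, with succinate signalling and metabolism named in the series title. Of the genes higher in the mimic group, Ascc3, a DNA helicase gene (ENSMUSG00000038774, chromosome 10, 50592669 to 50851485 on GRCm38), had the smallest p. It stood at 25.2 ± 5.35 CPM in NS control and 46.2 ± 5.02 CPM in mimic libraries (SD, n = 5 each). Top2a, the DNA topoisomerase of dividing cells, followed at 21.8 ± 4.14 and 40.2 ± 6.34 CPM. Depp1, a target of FOXO transcription factors linked to autophagy (ENSMUSG00000048489, chromosome 6, 116650609 to 116652794), had the smallest p of the genes lower in the mimic group once immunoglobulin genes, 5 of which had a smaller p, were left out. It stood at 21.9 ± 9.39 CPM in NS control and 5.50 ± 2.94 CPM in mimic libraries, a log2 fold change of −1.98 (SE 0.46). Klhdc2, a substrate receptor of a ubiquitin ligase, had a log2 fold change of −1.09 (SE 0.29), and the mitochondrial ubiquitin ligase gene March5 −0.90 (SE 0.26). The lysosomal hyaluronidase gene Hyal1 was at 0.501 of its NS control level. On the higher side, Cap1, a regulator of actin turnover, had a log2 fold change of 1.11 (SE 0.25). The kinesin motor gene Kif3b was at 0.96, the phospholipid flippase gene Atp8a1 at 0.94, the Mediator subunit gene Med23 at 0.85, Zfp106 at 0.82 and the sulfate transporter gene Slc26a2 at 0.70. Also lower in the mimic group were Ushbp1 at −2.03, the kinesin-binding protein gene Kif1bp at −0.89, Pxdc1 at −0.77 and the zinc transporter gene Slc39a3 at −0.62. Depp1 stood at 8.16 CPM in NS control 3 against 16.1 to 30.2 CPM in the other NS control libraries. Ushbp1, Kif1bp and Hyal1 were also lowest of the group there, as were the endothelial genes Cavin2 and Cldn5. Klhdc2, Pxdc1 and March5 were lowest in NS control 4 and Slc39a3 in NS control 5. Bulk libraries do not show which cells these transcripts came from.

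None of the genes named above passed the main test. The edgeR test called 0 genes higher and 0 lower of 19649, with a smallest adjusted p of 0.90 and 645 genes at an unadjusted p under 0.05, where 982 are expected by chance. DESeq2 called 4 genes higher and 7 lower, with 1122 at an unadjusted p under 0.05. The 4 were Kif3b, Ascc3, Top2a and Slc26a2 (adjusted p = 0.0134, 0.0213, 0.0295 and 0.00528). The 7 were Depp1 (adjusted p = 0.0431), the antibody heavy chain gene Ighg3 and the variable segments Igkv4-61, Igkv1-110, Igkv4-55, Ighv3-6 and Ighv1-47. The other edgeR and voom fits to all 10 libraries called 0 genes, with 552 to 4039 at an unadjusted p under 0.05. Without NS control 3, edgeR called 2 genes lower, Ighg3 and Ighv1-11. In simulated data of this design 10% of genes changed 2-fold were recovered and 90% of those changed 8-fold, so a change of about 2-fold was mostly not detectable.

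Among genes of succinate metabolism and the inflammasome, Nlrp3, the sensor that assembles the inflammasome (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956), was measured at 29.8 ± 19.5 CPM in NS control and 48.9 ± 23.2 CPM in mimic libraries (SD, n = 5 each). Its log2 fold change was 0.71, with a 95% interval from −0.29 to 1.70. Il1b, the cytokine matured by that complex (chromosome 2, 129364570 to 129371139), was at 892 ± 786 and 1040 ± 675 CPM, with a log2 fold change of 0.22 and an interval from −0.92 to 1.36. Acod1 makes itaconate, an inhibitor of succinate dehydrogenase (chromosome 14, 103046977 to 103056573). Its NS control level was 20.2 ± 7.76 CPM and its log2 fold change 0.66 (SE 0.30). The 4 subunit genes of succinate dehydrogenase, which oxidizes succinate, all had negative log2 fold changes: Sdha −0.27, Sdhb −0.19, Sdhc −0.20 and Sdhd −0.16. The hypoxia regulator Hif1a, the protease gene Casp1 and the cytokine genes Il18, Tnf and Il6 had log2 fold changes of −0.04, −0.03, 0.07, 0.12 and −0.01. Each of these 5 signs, and that of Il1b, turned under at least 1 alternative. With edgeR 0 of the 12 tested genes passed adjusted over the list alone (Acod1 adjusted p = 0.553) and 0 over all genes, and 1, Acod1, was at an unadjusted p under 0.05. DESeq2 called 0 of them, and voom with sample quality weights called 1, Nlrp3 (adjusted p = 0.00924 over the list alone).

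**Figure D2:**
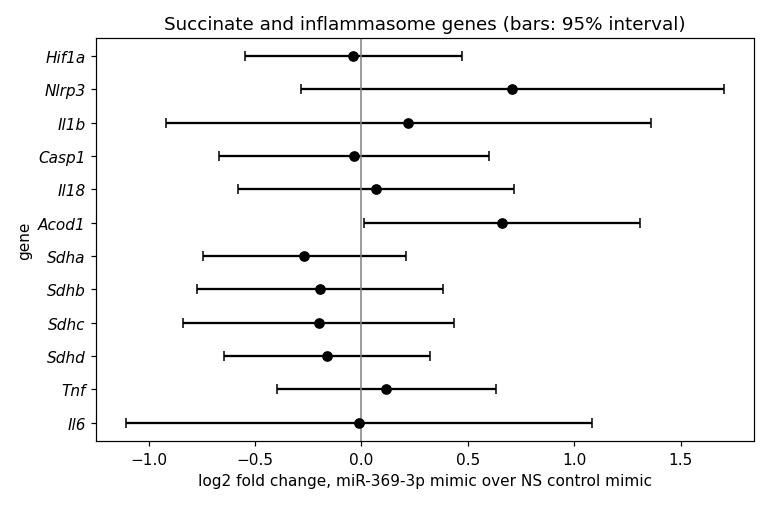
Log2 fold change of miR-369-3p mimic over NS control mimic for the 12 tested genes of succinate metabolism and inflammasome signalling (points) with 95% intervals (bars), n = 5 libraries per group. The interval of Acod1 runs from 0.01 to 1.31 and the other 11 include 0.

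Sucnr1, which encodes the cell surface receptor for succinate (ENSMUSG00000027762, chromosome 3, 60081869 to 60087566), had too few reads to be tested. It received 0, 5, 62, 0 and 16 counts in NS control libraries 1 to 5 and 0, 1, 0, 1 and 0 in the mimic libraries. Pooled, this was 83 counts or 0.751 CPM in the NS control group and 2 counts or 0.0207 CPM in the mimic group, a ratio of 0.0276 with an exact 95% interval of 0.00329 to 0.103 for counting error. NS control 3 alone gave 62 of the 83 counts, and without it 21 remained. The spread between libraries was wider than counting error, with 0 to 62 counts in NS control libraries. A two-sided exact permutation test of the group difference in log2(CPM + 1) gave p = 0.167. Fitted without a filter, edgeR gave Sucnr1 a log2 fold change of −4.96 and an adjusted p of 0.821 over all genes.

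Genes of mitochondrial energy metabolism were lower together by small amounts in the mimic group. Of 75 nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 68 had a negative log2 fold change and 7 a positive one, with a median of −0.18. Uqcrc1, a core subunit of the cytochrome bc complex (ENSMUSG00000025651, chromosome 9, 108936633 to 108949623), stood at 297 ± 89.1 CPM in NS control and 196 ± 46.2 CPM in mimic libraries (SD, n = 5 each). The NADH dehydrogenase subunit genes Ndufs7, Ndufb10 and Ndufa3 had log2 fold changes of −0.37, −0.33 and −0.28. Of 29 genes of succinate metabolism and the citric acid cycle, 25 were lower, with a median of −0.19. Among them were Idh3a at −0.50, Idh2 at −0.41, Sucla2 at −0.38 and Ogdh at −0.35. No member of either list passed alone: edgeR called 0 of 75 and 0 of 29 over all genes and adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05, and DESeq2 called 0. As a group, oxidative phosphorylation genes fell against all other genes (camera adjusted p = 4.09e-07, 68 of 75 lower). That call was lost when the correlation between the genes was taken from the data (adjusted p = 0.954 with an estimated correlation). The citric acid cycle list fell in the same way (camera adjusted p = 9.64e-04), with adjusted p = 0.954 with an estimated correlation. The oxidative phosphorylation score per library was 6.75 ± 0.21 in NS control and 6.55 ± 0.37 in mimic libraries (two-sided exact permutation p = 0.317, adjusted p = 0.881). NS control 4 and miR-369-3p mimic 5, with the most olfactory receptor reads, had the lowest oxidative phosphorylation scores of their groups. Smooth muscle transcripts were lower in the mimic group beside both lists, with Acta2 at 5036 ± 2264 CPM of the total counts in NS control and 2754 ± 1305 in mimic libraries.

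**Figure D3:**
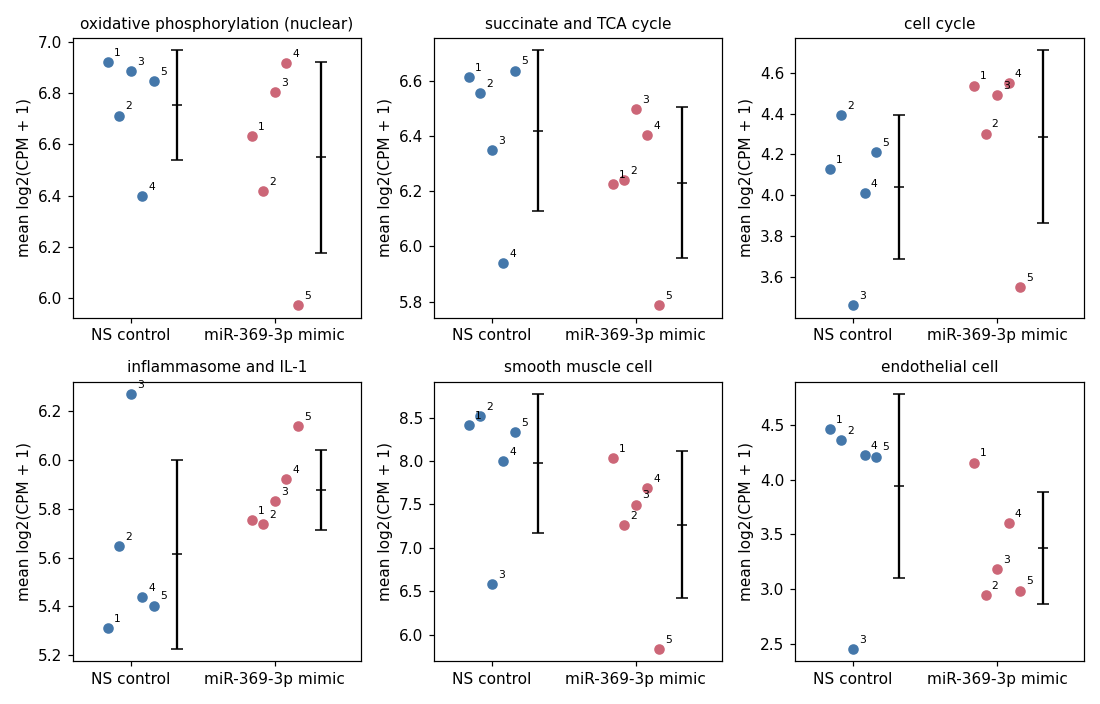
Mean log2(CPM + 1) over the members of 6 gene lists in each library (points, numbered by replicate), with the mean and SD of each group beside them (bars), n = 5 libraries per group. In the oxidative phosphorylation panel miR-369-3p mimic 5 lies lowest at 5.97, and in the endothelial and smooth muscle panels NS control 3 lies lowest of its group.

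Genes of the cell cycle were higher together in the mimic group. Of 36 members 28 had a positive log2 fold change, with a median of 0.20. Top2a was at 0.88 (SE 0.20), and Cenpf and Cenpe, kinetochore genes of mitosis, were at 1.18 and 0.91. The proliferation marker Mki67 stood at 19.4 ± 11.1 CPM in NS control and 33.3 ± 8.16 CPM in mimic libraries (SD, n = 5 each). Top2a passed with edgeR adjusted over the list alone (adjusted p = 0.0288) and 0 members passed over all genes, with 2 at an unadjusted p under 0.05; DESeq2 called 1, Top2a, over all genes. As a group the cell cycle genes rose against all others (camera adjusted p = 0.00218), with adjusted p = 0.954 with an estimated correlation. The camera call was also lost without NS control 3 (adjusted p = 0.0766), miR-369-3p mimic 3 (0.0755) or miR-369-3p mimic 4 (0.0560), with no filter (0.311), on voom values with sample quality weights (0.0512) and without the 4 libraries sharing antibody segments (0.637). NS control 3 had the lowest cell cycle score of all libraries, 3.46, and miR-369-3p mimic 5 the lowest of its group, 3.55.

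Inflammatory and interferon genes were mostly higher in the mimic group without passing the main test. Of 18 inflammasome and IL-1 genes 15 had a positive log2 fold change, among them the bacterial sensors Naip5 and Naip2 at 0.58 and 0.53 and the DNA sensor Aim2 at 0.46. Of 37 genes of the NF-kB response 24 were positive. In that list the chemokine gene Ccl4 stood at 532 ± 134 CPM in NS control and 849 ± 241 CPM in mimic libraries (SD, n = 5 each), Cxcl2 had a log2 fold change of 0.44, and Rela, a subunit of NF-kB itself, was at −0.77. Of 35 genes of the type I interferon response 24 were positive. The antiviral genes Oasl1, Ifih1, Ifit1 and Rsad2 were at 1.15 (SE 0.34), 0.98 (SE 0.32), 0.97 (SE 0.34) and 0.76 (SE 0.28). By edgeR 0 members of these 3 lists passed adjusted over the list alone or over all genes, with 0, 3 and 4 at an unadjusted p under 0.05, and DESeq2 called 0. The lists missed the threshold with camera (adjusted p = 0.0870, 0.272 and 0.310) and with an estimated correlation (adjusted p = 0.954 each). Without NS control 3, whose NF-kB score was the highest of all libraries, camera called the 3 lists higher (adjusted p = 1.35e-04, 4.53e-07 and 0.00497), as it did without miR-369-3p mimic 1 (0.0387, 0.0465 and 0.0452). With all 10 libraries camera called the inflammasome list higher with the stricter filter (adjusted p = 0.0262), and the inflammasome and NF-kB lists higher on voom values with sample quality weights (0.00804 and 0.0151).

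Genes of hypoxia, glycolysis and lipid handling differed both ways. Of 22 hypoxia targets 16 had a negative log2 fold change. The mitochondrial protein gene Higd1a was at −0.65 (SE 0.20), the stress gene Ndrg1 at −0.81 and the collagen hydroxylase gene P4ha2 at −1.11, against the histone demethylase gene Kdm3a at 0.49. In NS control 3, P4ha2 (8.64 CPM) and Ndrg1 (37.9 CPM) were the lowest of their group, as was the smooth muscle gene Cnn1 (151 CPM). Higd1a was lowest in NS control 4 and Kdm3a in NS control 5. Of 21 glycolytic genes 17 were negative, among them Pfkl at −0.52, Aldoa at −0.35 and Pgam1 at −0.28, with the lactate exporter gene Slc16a3 at 0.34. In a list of foamy Trem2 macrophages 13 of 25 genes were positive. There Fabp4, a fatty acid chaperone of macrophages and fat cells, stood at 94.8 ± 51.1 CPM in NS control and 38.1 ± 14.5 CPM in mimic libraries (SD, n = 5 each). The lipoprotein lipase gene Lpl was at 287 ± 40.5 and 377 ± 55.5 CPM, and Fabp5 and Cd9 had log2 fold changes of 0.41 and −0.56. Of 19 genes of cholesterol efflux and its regulator LXR 9 were positive. The exporter gene Abca1 was at 0.46, the LXR gene Nr1h2 at −0.38, Srebf1 at −0.40 and Apoc1 at −0.92. On voom values with sample quality weights Apoc1 turned to 0.043. The median of that list, −0.02, was negative while its mean of 0.02 and the camera direction were positive. Of 24 genes of cholesterol synthesis 8 were positive, with the feedback regulator Insig1 at 0.40, Srebf2 at 0.25, the rate-limiting enzyme gene Hmgcr at 0.24 and Msmo1 at −0.30. With edgeR 0 members of these 5 lists passed over all genes or adjusted over the list alone (3, 1, 2, 0 and 1 at an unadjusted p under 0.05), and DESeq2 called 0. Camera called none of the 5 lists in the main fit (adjusted p = 0.117, 0.0870, 0.824, 0.923 and 0.395). It called hypoxia targets and glycolysis lower on voom values with sample quality weights (adjusted p = 0.0198 and 0.0307), with no filter (0.00111 and 0.00114), and without NS control 4 (0.0190 and 0.00540), miR-369-3p mimic 3 (0.00847 and 0.00507) or miR-369-3p mimic 4 (0.0425 and 0.0126). Hypoxia targets were also called lower without NS control 3 (0.0389), and cholesterol synthesis with no filter (0.0222). Of the added fits, that without the 4 libraries sharing antibody segments called hypoxia targets, glycolysis and the foamy Trem2 list lower (0.00302, 1.31e-04 and 0.00627), and that without the 2 libraries richest in olfactory receptor reads glycolysis (0.0318). With an estimated correlation adjusted p was 0.954 for each of the 5 lists.

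Markers of cells other than macrophages were present, and those of the vessel wall were lower in the mimic group. Of 15 smooth muscle genes 14 had a negative log2 fold change, with a median of −0.86. The contractile genes Cnn1, Smtn, Myl9 and Tpm1 were at −1.10, −1.01, −0.99 and −0.87, and Myl9 stood at 1734 ± 883 CPM in NS control and 872 ± 400 CPM in mimic libraries (SD, n = 5 each). Of 15 endothelial genes 13 were negative, with a median of −0.52, among them Egfl7 at −1.17, the junction genes Esam and Cldn5 at −1.14 and −1.38, and Cavin2 at −1.28. Of 16 fibroblast genes 15 were negative, with a median of −0.65, among them the matrix genes Mfap5 at −0.97, Col6a2 at −0.75 and Bgn at −0.65, and Serpinf1 at −0.90. In each group 1 library lay far below the rest: Cnn1 was at 151 CPM in NS control 3 against 481 to 848 in the other controls, and at 83.0 in miR-369-3p mimic 5, rich in olfactory receptor reads, against 268 to 394 in the other mimic libraries. With edgeR and DESeq2 0 members passed over all genes, and with edgeR 0 adjusted over the list alone, with 1, 1 and 0 at an unadjusted p under 0.05. As groups the smooth muscle, endothelial and fibroblast genes fell against all others (camera adjusted p = 4.72e-05, 0.00295 and 0.0343), with adjusted p = 0.954 with an estimated correlation for each. The endothelial call was lost without miR-369-3p mimic 2 (adjusted p = 0.0529) or the 4 libraries sharing antibody segments (0.134), and the fibroblast call without NS control 1 (0.239), NS control 4 (0.177), NS control 5 (0.117) or miR-369-3p mimic 5 (0.564). The fibroblast call was also lost with RLE factors (0.0681), with the stricter filter (0.0854), and without those 4 libraries (0.116) or the 2 richest in olfactory receptor reads (0.980).

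Macrophage genes differed both ways, and genes of antigen presentation were mostly higher. Of 17 macrophage identity genes 9 had a positive log2 fold change. The chemokine receptor gene Cx3cr1 stood at 54.6 ± 13.3 CPM in NS control and 85.2 ± 15.4 CPM in mimic libraries (SD, n = 5 each). The protease gene Lgmn was at 0.37, Adgre1, a macrophage surface receptor gene, at 0.28 and the complement gene C1qa at 0.26. Of 21 genes of resident-like macrophages 9 were positive, with the chemokine gene Ccl8 at 0.60, the mannose receptor gene Mrc1 at 0.41, Gas6 at −0.45 and the lectin gene Fcna at −0.37. Fcna stood at 391 CPM in NS control 3 against 124 to 160 CPM in the other NS control libraries. Its sign turned in a fit with 1 library left out. NS control 3 also had the highest Ccl8 and Mrc1 of its group. In that list the median of −0.03 and the mean of −0.01 were negative while camera gave the direction up (adjusted p = 0.608). Of 12 genes of antigen presentation on MHC class II 10 were positive, with H2-Ob at 0.40, H2-Oa at 0.37, H2-Eb1 at 0.25 and the regulator Ciita at 0.22. With edgeR 0 members of these 3 lists passed over all genes or adjusted over the list alone (1, 0 and 0 at an unadjusted p under 0.05), and DESeq2 called 0. In the main fit camera called neither macrophage identity (adjusted p = 0.294) nor antigen presentation (0.182), and the 3 tests with an estimated correlation gave adjusted p = 0.954 each. Without NS control 3 camera called the 3 lists higher (adjusted p = 1.21e-04 for macrophage identity, 5.08e-06 for resident-like macrophages and 0.00166 for antigen presentation). On voom values with sample quality weights it called macrophage identity and resident-like macrophages higher (0.00932 and 0.0307), and without miR-369-3p mimic 1 antigen presentation (0.0170). Without miR-369-3p mimic 1 it called 14 lists, among them those of B cell genes and of T and NK cell genes as higher (9.77e-04 each). That library had the lowest B cell score of its group, 3.53, and the lowest H2-Ob value, 31.1 CPM. Bulk libraries do not show which cells the antigen presentation transcripts came from. Camera called macrophage identity and resident-like macrophages lower (0.00710 each) without NS control 4 and 5 and miR-369-3p mimic 3 and 4. These share antibody segments with NS control 2 and mimic 2, which were kept. In that fit Adgre1, C1qa, H2-Eb1 and Ciita turned to −0.12, −0.16, −0.13 and −0.024, and the other genes named here kept their signs.

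Antibody genes set libraries of the same group apart. Among B cell genes the light chain constant genes Iglc2 and Igkc were at log2 fold changes of −1.89 and −1.44, and the B cell surface genes Cr2 and Ms4a1 at 1.53 and 0.81. Ms4a1 stood at 113 CPM in miR-369-3p mimic 5 against 7.65 to 56.1 CPM in the other mimic libraries. Its log2 fold change turned to −0.22 on voom values with sample quality weights. In that list 13 of 17 were positive, edgeR and DESeq2 called 0, 1 was at an unadjusted p under 0.05 with edgeR, and the camera adjusted p was 0.566, against 9.77e-04 without miR-369-3p mimic 1 and 0.954 with an estimated correlation. The kappa variable segment Igkv4-61 took 82.1% of all kappa variable reads in NS control 2 (95% Wilson interval 81.7 to 82.4), 39.3% in NS control 4 (38.2 to 40.3) and 49.3% in NS control 5 (48.7 to 49.95). Igkv4-91 took 30.3% in miR-369-3p mimic 2 (29.5 to 31.1), 29.5% in mimic 3 (28.8 to 30.3) and 27.0% in mimic 4 (26.1 to 28.0). Segment use correlated above 0.9 across both kappa and heavy segments in 6 of 20 pairs of libraries of the same group and in 0 of 25 pairs between groups. These correlations are across segments, which are not independent replicates. The 6 pairs lay among NS control 2, 4 and 5 and among miR-369-3p mimic 2, 3 and 4. Below that bound, correlations between groups reached 0.35 for kappa and 0.62 for heavy segments. Ighv11-2 took 27.0% of heavy variable reads in NS control 1 and 27.1%, 25.4% and 24.6% in miR-369-3p mimic 2, 3 and 4. Igkv14-126 took 22.4% of kappa variable reads in NS control 1 and 21.3%, 20.6% and 20.1% in those mimic libraries. Igkv4-91, by contrast, took 0.46% in NS control 1. Igkv4-61, called lower by DESeq2, stood at 459 ± 604 CPM in NS control and 1.29 ± 1.18 CPM in mimic libraries.

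**Figure D4:**
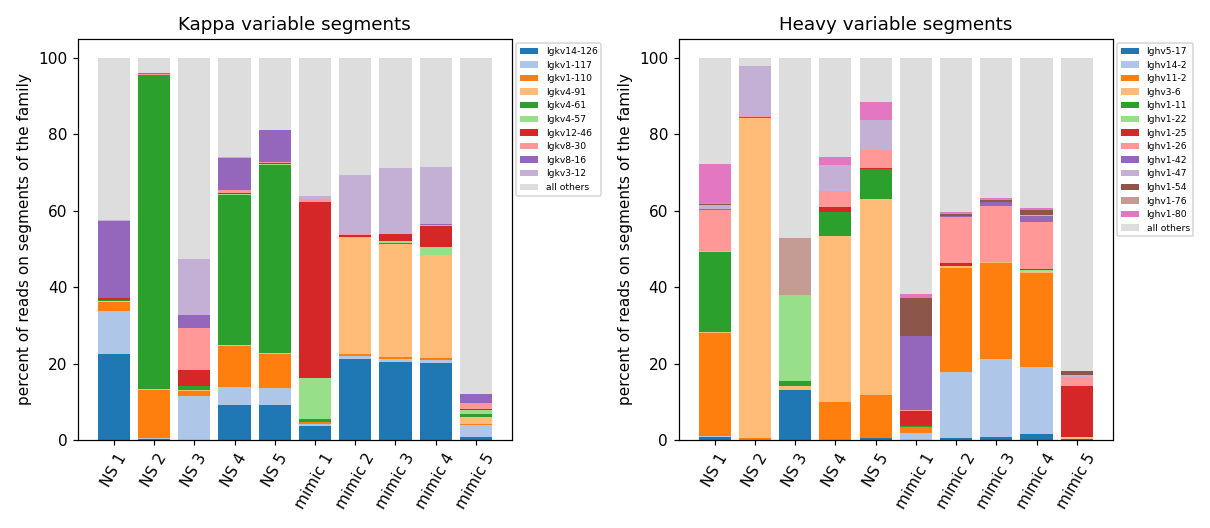
Percent of reads on kappa variable segments (left) and heavy variable segments (right) taken by each segment that reached 10% in any library, with all others in grey, per library. NS control 2, 4 and 5 share Igkv4-61 as their most used kappa segment, and miR-369-3p mimic 2, 3 and 4 share Igkv4-91.

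Genes with a miR-369-3p site in the 3′ UTR did not have a lower mean log2 fold change than genes without one. The seed of the microRNA pairs with the word GTATTAT, and 1529 tested genes held it while 13696 searched genes did not. Their mean log2 fold changes were 0.26 and 0.06, a difference of 0.20. The other words of the same base composition gave differences from 0.14 to 0.25 with a median of 0.19, and the two-sided rank p of the seed word among all words of that composition was 0.686. Among genes with a mean of at least 5 CPM the difference was 0.16, with 9 of the other words lower against 72 among all tested genes. There the seed word had a two-sided rank p of 0.143. Genes with the word had longer 3′ UTRs, with a median of 2517 against 1037 nucleotides. Kif3b, Ccl4, Abca1, Hmgcr, Ifih1 and H2-Ob each had 1 site and a positive log2 fold change, and Cavin2, Eif2s3y and Ddx3y had 1, 1 and 2 sites and log2 fold changes of −1.28, −0.83 and −0.57. The 3′ UTR of Sucnr1, 560 nucleotides long, held 0 sites. The difference was 0.02 without miR-369-3p mimic 5 and 0.32 without NS control 4, and it stayed inside the range of the other words in both.

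**Figure D5:**
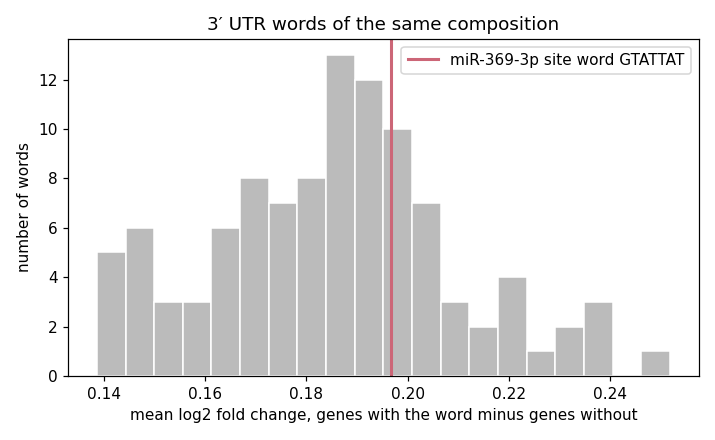
Difference in mean log2 fold change between genes with and without a 3′ UTR word (horizontal axis) and the number of words at each difference (vertical axis) for the other words of the base composition of the miR-369-3p site. The red line marks the site word at 0.20, inside the range of 0.14 to 0.25 of the others.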

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

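The tests of transcripts of more cell types, of list genes varying together and of a lower immunoglobulin level under the mimic were chosen only after the result was seen, as was the set of measures searched for libraries apart from their group.

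Libraries far from the other 4 of their group were searched for with Dixon's ratio at 0.71 in 300 groups of 5 values, which came from library measures, list scores and named genes. Chance marks about 1 in 20 such groups, so 15 were expected, and 57 values were found. Of these, 27 lay in miR-369-3p mimic 5, 18 in NS control 3 and 6 in NS control 4; many of the genes and lists vary together, so the values are not independent.

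NS control 4 and miR-369-3p mimic 5 carried reads on genes that macrophages keep silent. Their totals were the lowest of their groups, at 10220000 and 4001000 counts, Gm10800, a repeat-like locus, took 1.36% and 2.32% of the counts, and gene models awaiting experimental evidence took 0.592% and 1.67%; the log2 olfactory receptor CPM of NS control 4 was 11.55. Lower depth was argued against. With every library thinned to the shallowest, NS control 4 and mimic 5 still held 34344 and 31607 detected genes, against at most 29217 elsewhere. More transcripts of the listed cell types were argued against, since the higher of their other-cell-type scores, 5.002, was below the 5.57 of NS control 1. That score covers lists of immune, vessel wall, fat and blood cells, so cell types without a list stay open. Genomic DNA among the sequenced molecules stays open: its test, olfactory receptor reads (2998 CPM in the lower of the libraries against at most 728 elsewhere), measures the pattern itself and so does not support it. Beyond that of cell types no biological explanation was tested, because the libraries belong to different groups.

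Oxidative phosphorylation genes were lower in the mimic group, with a median log2 fold change of −0.18. With the smooth muscle score in the model the median was −0.09, 47.4% of its size, and with the log2 olfactory receptor CPM it was −0.05, 29.7% of its size; both had been predicted to fall under 50% if fewer smooth muscle cells or genomic DNA were the cause. Camera still called the list in both fits (adjusted p = 0.00178 with 59 of 75 genes lower, and 0.0368 with 45 of 75), but at the preset correlation, so both explanations stay open. The citric acid cycle list lost its call in both (adjusted p = 0.115 and 0.120), as its median of −0.19 (quartiles −0.26 and −0.09) shrank to −0.06 (−0.17 and −0.002) and −0.08 (−0.14 and 0.06), while the cell cycle median rose from 0.20 to 0.50 and 0.30. In the fit without the 2 libraries richest in olfactory receptor reads, camera called both lists lower (adjusted p = 6.48e-07 and 5.5e-05). At the preset correlation, neither call thus depended on those 2 libraries. That the oxidative phosphorylation genes vary together between libraries also stays open. The exact permutation test of their list score gave p = 0.317, and their estimated correlation was 0.728. An effect of the mimic stays possible and was not separated from these.

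Immunoglobulin genes differed between libraries: the log2 immunoglobulin CPM of NS control 3 was 8.98, the log2(CPM + 1) of Igkc in that library was 5.53 and that of Iglc2 in miR-369-3p mimic 1 was 2.52, each far below the rest of its group. A lower level under the mimic cannot be told apart from the spread between libraries, with a log2 difference of −0.79 and an exact permutation p of 0.341. Material shared between libraries of a group stays open: as mixtures of whole libraries, the pair of the same group ranked first of 15 pairs in 1 of 4 libraries, NS control 5, but for 3 of the 4 the library closest in segments was not among the sources, so the ranking excludes nothing. Few plasma cells per sorted sample may account for the dominant segments. In 7 of 10 libraries 25% or more of the kappa variable reads lay on 1 segment, and 6 different segments led. That account does not by itself predict the same segments in several libraries of a group or, as for Ighv11-2, of both groups. Sharing of mice or of plasma cells alone was not tested, and if present it would make libraries of a group less independent than the tests assume.

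Other values stood apart, on the log2(CPM + 1) scale for genes and as its mean for lists. In miR-369-3p mimic 5 the scores of hypoxia targets (4.46), LXR and cholesterol efflux (5.97), cholesterol biosynthesis (4.22), cell cycle (3.55) and fibroblast genes (4.49) were the lowest of the group. Its values were also the lowest of the group for the metabolic genes Ndufs7 (5.85), Idh2 (6.02), Idh3a (4.15), Pgam1 (4.90), Nr1h2 (5.25) and Srebf1 (4.88). The same held for the vessel wall genes Cnn1 (6.39), Smtn (6.05), Tpm1 (6.4), Col6a2 (3.83), Mfap5 (2.99) and Bgn (6.84), and for the hypoxia target P4ha2 (3.41). Its values of Gas6 (7.88), Mrc1 (9.53), Hyal1 (3.18), Xist (3.38) and Ldlr (5.38) were the lowest of the group and that of Il1b (11.12) the highest. In NS control 3 the scores of the NF-kB response (7.46), resident-like macrophages (9.21), alternative activation (7.10) and monocytes (6.47) were the highest of the group, and those of smooth muscle (6.59) and endothelial genes (2.45) the lowest. In that library Il1b (11.16), Ccl8 (8.87), Mrc1 (10.39), Fcna (8.62), Ciita (6.12) and C1qa (10.83) were the highest of the group. Cavin2 (2.60), Cldn5 (1.40), Bgn (7.64) and Xist (0.068) were the lowest there. In NS control 4 Sdha (7.61) and Sdhb (7.02) were the lowest of the group. The mitochondrially encoded score of NS control 2 was 6.61 and the sex-linked score of NS control 1 was 1.25, both the lowest of the group. In miR-369-3p mimic 1 the B cell score (3.53) and H2-Ob (5.01) were the lowest of the group, and in miR-369-3p mimic 2 Acod1 (4.28) was.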

How the results depend on the processing

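The fits without 2 libraries rich in silent-gene reads (NS control 4, miR-369-3p mimic 5) and without 4 libraries sharing immunoglobulin segments (NS control 4 and 5, mimic 3 and 4) were chosen after seeing the data. The latter fit kept NS control 2 and miR-369-3p mimic 2, which share the same segments. Of 106 named genes 90 kept their sign in every alternative run, and of 2014 values 44 reversed; the cause was not tested. No list score passed adjustment in any alternative. The replicate block and the fit without the 4 libraries could not pass, since their few permutations cannot give a p under 0.05. Their smallest unadjusted exact permutation p were 0.188 and 0.1. Without NS control 3, 5 list scores were at an unadjusted exact permutation p under 0.05, with a smallest adjusted p of 0.176. The difference for seed sites was positive in every alternative, from 0.02 to 0.32 with 1 library left out, 0.12 without the 2 libraries and 0.38 without the 4. The median log2 fold change of all genes was 0.04 with TMM, 0.11 with library size only and 0.16 with no filter. The replicate numbers did not pair the libraries: 1 of 5 same-number correlations exceeded 0.1. Of genes above 5 CPM, simulated as independent with a 2-fold change, 10% were recovered, with a 4-fold change 68% and with an 8-fold change 90%.

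DESeq2 called 4 genes higher and 7 lower, and gave Casp1 0.012 and Il6 0.084. RLE factors gave Casp1 0.012 and Il6 0.077, and the fibroblast adjusted p was 0.0681. Library size only gave Hif1a 0.056, Casp1 0.079 and Il6 0.15. The stricter filter gave Hif1a 0.014, Casp1 0.017 and Il6 0.067, and the fibroblast adjusted p was 0.0854. Voom with sample quality weights called 1 succinate and inflammasome gene, Nlrp3, and 14 lists, gave the cell cycle an adjusted p of 0.0512, and gave Hif1a 0.047, Casp1 0.062, Apoc1 0.043, Ms4a1 −0.22 and mt-Co1 −0.018. The replicate block gave Casp1 0.018 and Il6 0.13. With no filter 15 lists were called and the cell cycle adjusted p was 0.311. With an estimated correlation 0 lists were called (adjusted p = 0.954 for oxidative phosphorylation, succinate and TCA cycle, cell cycle, smooth muscle, endothelial and fibroblast lists) and with fry 0 (adjusted p = 0.880 for the same 6); the estimated correlations of these lists ran above the preset 0.01. Without the 2 libraries edgeR called 0 genes (1434 at an unadjusted p under 0.05) and camera 8 lists, Il1b was −0.38 and the fibroblast adjusted p was 0.980. Without the 4 libraries edgeR called 0 genes (2567 at an unadjusted p under 0.05) and camera 15 lists, 3 of them among the 6, the adjusted p was 0.637 for the cell cycle, 0.134 for endothelial and 0.116 for fibroblast genes, and Il18 was −0.39, Tnf −0.34, Ciita −0.024, H2-Eb1 −0.13, Adgre1 −0.12, C1qa −0.16 and mt-Co1 −0.39.

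With each library left out in turn, 0 to 2 genes were called lower (2 without NS control 3) and 6 to 15 lists were called: 12 without NS control 2, 15 without NS control 3, 11 without NS control 4, 14 without mimic 1, 11 without mimic 3 and 12 without mimic 4. Genes at an unadjusted p under 0.05 numbered 2506 without NS control 4, 1307 without NS control 3, and 321, 407 and 357 without NS control 1, 2 and 5, against 645. The adjusted p ran from 2.79e-16 to 0.00195 for oxidative phosphorylation, 1.78e-06 to 0.0158 for succinate and TCA cycle, 2.11e-05 to 0.0766 for cell cycle, 1.09e-10 to 0.00234 for smooth muscle, 2.09e-09 to 0.0529 for endothelial and 2.41e-06 to 0.564 for fibroblast genes. The log2 fold change ran from −0.18 to 0.094 for Hif1a, −0.26 to 0.90 for Il1b, −0.18 to 0.25 for Casp1, −0.17 to 0.36 for Il18, −0.089 to 0.26 for Tnf, −0.30 to 0.47 for Il6, −0.53 to 0.067 for Fcna, −1.80 to 0.042 for Ddx3y, −1.77 to 0.23 for Kdm5d and −0.10 to 0.30 for mt-Co1.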

Other observations

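The lists and genes described in this part were picked after their values were seen, and the counts over other splits were planned before, except that of the oxidative phosphorylation list, which was chosen after.

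Cell types beyond those of the vessel wall also differed between libraries. Of 8 mast cell genes 8 had a positive log2 fold change, with a median of 0.57, and of 11 adipocyte genes 7, with a median of 0.51. Of 11 erythroid and platelet genes 9 were negative, with a median of −1.17; the haemoglobin genes Hbb-bs and Hba-a1, which mark red cells, stood at 419 ± 412 and 736 ± 684 CPM in NS control and 167 ± 103 and 289 ± 169 CPM in mimic libraries (SD, n = 5 each). Of 14 neutrophil genes 9 were negative, with a median of −0.19. By edgeR 0 genes of these 4 lists passed over all genes or adjusted over the list alone, with 1, 0, 0 and 0 at an unadjusted p under 0.05, DESeq2 called 0, and camera gave adjusted p = 0.191, 0.608, 0.154 and 0.154. Of 87 genes of cytosolic ribosomal proteins 67 were positive, with a median of 0.07 (camera adjusted p = 0.294). Of 13 mitochondrially encoded genes 10 were negative, with mt-Co1, a subunit of cytochrome oxidase, at 0.15, and camera gave adjusted p = 0.656. The sign of mt-Co1 turned on voom values with sample quality weights (−0.018) and without the 4 libraries sharing antibody segments (−0.39). It also turned in a fit with 1 library left out. Under alternatives camera called mast cell genes higher without miR-369-3p mimic 1 (adjusted p = 0.00738) or mimic 5 (0.0129). It called erythroid and platelet genes lower with no filter (0.00819), on voom values with sample quality weights (0.00288) and without NS control 2 (3.36e-04) or NS control 3 (0.00287). Neutrophil genes were called lower with no filter (0.00958) and without NS control 2 (5.66e-05) or mimic 5 (0.0369), and mitochondrially encoded genes without NS control 2 (5.66e-05). Cytosolic ribosomal proteins were called both ways. They were higher with the stricter filter (0.0165), with quality weights (0.00932), without NS control 3 (6.08e-04), mimic 2 (0.00988) or mimic 5 (0.00334), and without the 2 libraries rich in silent-gene reads (5.58e-04). They were lower without NS control 2 (0.0334) or mimic 4 (0.0425), and without the 4 libraries sharing antibody segments (0.00225). With an estimated correlation adjusted p was 0.954 for each of these lists.

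Transcripts of both sexes were found within single libraries, and the labels give no sex and no number of mice per library. The n = 5 of each group therefore counts libraries, which may hold RNA of more than 1 mouse. The balance of these transcripts differed between libraries, and its part in their spread was not tested. Xist, transcribed from the inactive X chromosome of females, and Ddx3y, a gene of the Y chromosome, both stood above 1 CPM of the total counts in 7 libraries, and NS control 3 had Xist at 0.0405 CPM beside Ddx3y at 118. In NS control 2, 4 and 5 Xist stood at 33.4, 57.1 and 61.3 CPM of the total counts and Ddx3y at 77.4, 37.2 and 26.1. In miR-369-3p mimic 1, 3, 4 and 5 Xist stood at 90.8, 114, 123.4 and 10.5 and Ddx3y at 34.1, 3.80, 26.5 and 142. The log2 fold changes of Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were 0.98, −0.57, −1.44, −0.99 and −0.83, and edgeR called 0 of them, with 0 at an unadjusted p under 0.05, as did DESeq2.

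Other splits of the libraries into 5 and 5 gave results as large as the real one for genes at an unadjusted p under 0.05, for lists called and for oxidative phosphorylation, so chance cannot be excluded for these results. The count of genes called by edgeR decides nothing, since the real split gave 0 and all 100 splits must give as many; the highest of the others was also 0. For genes at an unadjusted p under 0.05, 56 of 100 splits gave as many as the real 645, and the highest of the others gave 4319. For lists called at the preset correlation, 96 of 100 splits gave as many as the real 6, and the highest of the others gave 28. For the camera adjusted p of oxidative phosphorylation, 33 of 100 splits gave one as small as the real 4.09e-07, the smallest of the others was 1.06e-30, and 70 of 100 passed 0.05. Splits with several times the real count show a structure among the samples that the groups do not follow; the first principal component held 49.3% of the variance, and miR-369-3p mimic 5 and NS control 4 lay at its upper end.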
